A study of Mus musculus with 12 samples.

How the data were processed

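RNA from cultured mouse bone marrow progenitors was measured on 12 gene arrays, 3 in each of 4 groups formed by virus (Myc or GFP) and Zfx genotype (wt or ko). Groups were taken from the sample titles, since the treatment text is the same for Myc and GFP samples and does not tell them apart. The deposited table holds 1 intensity per probe set and array, made by the authors with RMA (background correction, quantile normalization and a summary over probes) per the submitters' processing notes; the software and its version are not given in the sources used here. The analysis plan took these values to be on the log2 scale, but the table is on a linear scale, so log2 was taken before every fit and no pseudocount was added.

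Of 35556 probe sets, 21789 have exactly 1 gene symbol, 1621 have several and 12146 are not listed in the gene table. Probe sets with 1 symbol were reduced to 1 per gene, the one with the highest mean over the 12 arrays, which left 19938 genes. No filter on dim probe sets was applied. Gene names were matched to a RefSeq table by identifier; probe positions and a genome were not used here.

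Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with a mean for each of the 4 groups over all 12 arrays and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Every adjusted p of a gene comes from this fit unless a block is named. The contrasts were the Myc effect in each genotype, the Zfx effect under each virus, their averages, and the interaction. Fold intervals are 95% intervals of single genes and are not adjusted. Sets of genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. There were 30 lists, of which 29 had at least 5 measured members and entered camera. Camera with a preset correlation of 0.01 passed lists in every contrast, and camera with an estimated correlation passed 0 lists in every contrast.

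Whether replicate numbers pair the arrays was checked on the values, since the labels give only the numbers. Deviations from the group means correlated at 0.40 to 0.85 between same-numbered arrays of different groups (median 0.64, 18 pairs) and at a median of -0.42 between different numbers. Deviations cancel within a group, so the negative median follows in part from taking them from the group means. Each of the 12 arrays was closest, among arrays of other groups, to an array of its own number. The numbers were therefore read as pairing the arrays, and a fit with the replicate number as a block is given beside the plan's fit where it changes a call or moves a count by more than 1.5 times. Nothing in the labels says whether equal numbers are 1 animal, 1 culture or 1 day, so the p-values measure the spread between arrays. Within a group, log2 values of replicates correlated at 0.9846 to 0.9926, and 0 pairs of arrays were identical. With 3 arrays per group and 8 residual degrees of freedom, the number of arrays limits the precision. Tested on simulated data built on these arrays, the fit for the Zfx effect with GFP called 61.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 0 unchanged genes; with the block it called 77.6%, 97% and 10 unchanged genes. For a change in 1 group the interaction called 37.3% at 1.5-fold and 74.6% at 2-fold, and 58.2% and 91% with the block. The simulation gave each replicate number the same effect in all groups, as the block assumes, so the gain with the block is partly built in. It also changed far fewer genes than were called for the Zfx effect, so these percentages need not hold for the data.

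Genes are named by a rule set beforehand: Zfx, Zfy1, Zfy2 and Myc everywhere, and Idh2 and Ptpmt1 in the Zfx comparisons; per comparison the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap between groups; the 5 lowest p where fewer than 5 pass; and up to 4 members past the threshold per list. Predicted genes, microRNA and small nucleolar RNA genes and receptors for smell were not named. The alternatives tried were the replicate block, a second quantile normalization, centring of arrays on their medians, a trended and robust variance prior, array weights, only the groups compared, only genes above the median intensity of all probe sets, all probe sets, a 2-fold minimum, an estimated correlation in camera, and leaving out each array in turn.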

Results

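Gene expression was measured on 12 arrays of RNA from cultured mouse myeloid progenitors, in 4 groups of 3 arrays. The cells were c-Kit+ bone marrow progenitors of tamoxifen-treated mice that carried CreER, a Cre recombinase that tamoxifen activates, and either a wild-type or a floxed copy of Zfx, an X-linked zinc finger transcription factor. Arrays of the floxed genotype are labelled Zfx ko and the others Zfx wt, and both names rest on the submitters' labels. Cells of each genotype were infected with a retrovirus that carried Myc and GFP or with a control virus that carried GFP. GFP+ cells were sorted after 48 hours and grown for 4 more days with IL-3, IL-6 and SCF at 10 ng/mL each. The deposited table held 35556 probe sets per array. The median intensity of an array lay between 127 and 137, the lowest value between 17.7 and 18.9, and the highest between 22320 and 24490. The comparisons below cover 19938 genes with 1 probe set each. The series asks how deletion of Zfx affects the gene expression that Myc induces.

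The Zfx probe set (10605729, chromosome X) was not lower in the arrays labelled Zfx ko. With the GFP virus its mean intensity was 946 ± 72.9 (SD, n = 3) in Zfx wt and 1020 ± 64.9 in Zfx ko. With the Myc virus it was 992 ± 26.4 in wt and 1050 ± 63.2 in ko. The log2 difference between ko and wt was 0.11 with GFP (limma adjusted p = 0.619, higher in 2 of 3 same-numbered pairs) and 0.08 with Myc (adjusted p = 0.789, higher in 3 of 3 pairs). The table does not say which part of the transcript the probes cover. Its Y-linked relatives gave low signals in every group, at mean intensities of 35.9 to 36.5 for Zfy1 and 26.8 to 28 for Zfy2, and neither passed the threshold in any comparison. The Myc probe set (10424400, chromosome 15) rose with the Myc virus, from 3010 ± 197 to 5230 ± 343 in wt and from 2700 ± 145 to 5050 ± 260 in ko. That was 1.74-fold in wt (95% interval 1.55 to 1.94, adjusted p = 7.24e-04) and 1.87-fold in ko (1.67 to 2.09, adjusted p = 3.42e-04), each in 3 of 3 pairs. Between genotypes the Myc probe set differed by -0.16 ± 0.07 (log2, SE) with GFP (adjusted p = 0.367; 0.0395 with the replicate number as a block) and by -0.05 ± 0.07 with Myc (adjusted p = 0.911; 0.562 with the block). Both differences were negative in 3 of 3 pairs.

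**Figure D1:**
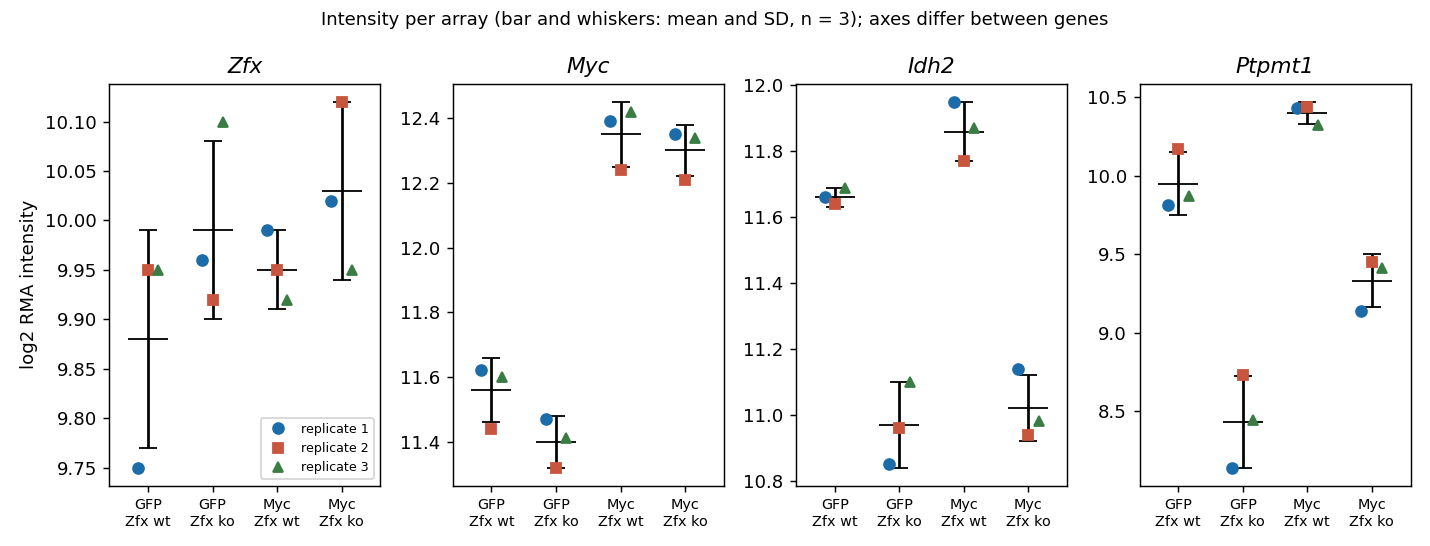
Log2 intensity of Zfx, Myc, Idh2 and Ptpmt1 on each array, by virus and genotype, with the mean and SD of 3 arrays per group (symbols give the replicate number, and the vertical axes differ between genes). Zfx means lie between 9.88 and 10.03 in the 4 groups, Myc is higher with the Myc virus in both genotypes, and Idh2 and Ptpmt1 are lower in Zfx ko with both viruses.

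Adding Myc to wt cells raised genes for making ribosomes, nucleotides, tRNA synthetases and mitochondrial ribosomes, and lowered genes of mature neutrophils and mast cells. This comparison asks what Myc does when Zfx is labelled intact. The largest rise was in Homer2, a synaptic scaffold gene, at 4.21-fold (95% interval 2.42 to 7.32, adjusted p = 6.87e-03). It was followed by Tet1, which oxidises methylated cytosine in DNA, at 3.59-fold (adjusted p = 6.32e-03), and by the Wnt receptor gene Ryk at 3.35-fold (adjusted p = 6.32e-03). Slc6a15, Car12, Hpdl, Spire1, Zdhhc23, Reep6 and Nefh rose between 2.82-fold and 3.34-fold. The largest fall was in Mcpt2, a mast cell protease gene, which was 12-fold lower (5.25 to 27.2, adjusted p = 4.08e-03). Gzmb, which encodes granzyme B, was 6.62-fold lower (adjusted p = 1.66e-02) and Mcpt1 was 4.93-fold lower (adjusted p = 9.81e-03). Serpinb10, Ceacam10, AA467197, Inhba, Trp53inp2, Ankrd22 and Plbd1 fell between 3.44-fold and 4.89-fold.

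Of 44 measured ribosome biogenesis genes, 39 rose and 0 fell with Myc in wt, and 43 rose when adjusted over the list alone. Rrp9 rose 1.89-fold, Nop14 1.7-fold, Tsr1 1.68-fold and Polr1b, a subunit of RNA polymerase I, 1.66-fold. The list's median log2 change was 0.60, with 0.60, 0.46 and 0.69 in pairs 1, 2 and 3 (camera adjusted p = 2.16e-34; adjusted p = 0.17 with an estimated correlation). Nucleotide synthesis had 15 of 26 genes up and 0 down, and 19 up adjusted over the list alone, with a median of 0.51 (camera adjusted p = 2.67e-13; 0.17 as adjusted p with an estimated correlation). Mthfd1l, a folate enzyme of mitochondria, rose 1.59-fold, Mthfd1 1.56-fold and Dhodh, of pyrimidine synthesis, 1.56-fold. Among 18 cytosolic tRNA synthetases 12 rose and 0 fell, and 18 rose adjusted over the list alone (median 0.40, camera adjusted p = 7.38e-13; adjusted p = 0.17 with an estimated correlation). Lars rose 1.44-fold and Gars 1.36-fold. In the mitochondrial ribosome 27 of 74 genes rose and 0 fell, and 52 rose adjusted over the list alone and 51 with the block (median 0.30, camera adjusted p = 7.42e-21; adjusted p = 0.17 with an estimated correlation), with Mrps27 at 1.59-fold and Mrpl47 at 1.57-fold.

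The citrate cycle, oxidative phosphorylation and glycolysis lists also rose as sets in wt at the preset correlation, with medians of 0.20 to 0.28. Citrate cycle genes rose in 8 of 13 cases, 9 adjusted over the list alone, and none fell (median 0.26, camera adjusted p = 2.56e-07; adjusted p = 0.17 with an estimated correlation). Suclg2, a succinyl-CoA ligase subunit, rose 1.61-fold and Suclg1 1.3-fold. Oxidative phosphorylation had 6 of 30 genes up and 0 down, and 16 up adjusted over the list alone (median 0.20, camera adjusted p = 4.22e-09; adjusted p = 0.17 with an estimated correlation). In glycolysis 5 of 15 genes rose, 9 adjusted over the list alone, and 0 fell (median 0.28, camera adjusted p = 4.42e-05; adjusted p = 0.25 with an estimated correlation). Slc16a1, which exports lactate, rose 1.58-fold and Pfkl 1.51-fold. The amino acid and integrated stress response list had 6 of 19 genes up and 0 down, and 8 up and 1 down adjusted over the list alone (median 0.22, camera adjusted p = 4.46e-04; adjusted p = 0.26 with an estimated correlation). Its largest rise was Stc2 at 2.4-fold, and Aldh18a1, of proline synthesis, rose 1.4-fold. Of 3 measured polyamine genes 1 rose, the spermidine synthase gene Srm at 1.34-fold, and 2 rose adjusted over the list alone. The proteasome list was past the threshold as a set (median 0.16, camera adjusted p = 5.36e-05; adjusted p = 0.50 with an estimated correlation), with 1 of 39 genes up, Psma8, also 1 adjusted over the list alone, and 13 up and 1 down with the block. DNA replication had 2 of 35 genes up, Orc1 and Pola2, and 1 adjusted over the list alone (median 0.09, camera adjusted p = 0.0166; adjusted p = 0.53 with an estimated correlation). With the block 15 oxidative phosphorylation, 9 glycolysis, 2 polyamine and 5 DNA replication genes rose, as did 9 of the amino acid and integrated stress response list, where 1 fell.

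Among the cell type lists in wt, neutrophil maturation fell most. Of its 19 measured genes 8 fell and 0 rose, and 17 fell adjusted over the list alone. The median log2 change was -0.85, with -1.36, -0.46 and -1.03 in pairs 1, 2 and 3 (camera adjusted p = 3.62e-14; adjusted p = 0.17 with an estimated correlation). Ltf, which encodes lactoferrin, was 3.1-fold lower, the integrin gene Itgam 2.49-fold lower and S100a9 1.97-fold lower. The mast cell and basophil list had 6 of 15 genes down and 1 up, and 7 down and 1 up adjusted over the list alone (median -0.63, camera adjusted p = 4.42e-05; adjusted p = 0.25 with an estimated correlation). Mcpt2, Mcpt1 and Tpsab1 fell, while Ms4a2, the beta chain of the IgE receptor, rose 2.35-fold (adjusted p = 1.08e-02). The primary granule list had 1 of 6 genes down, also 1 adjusted over the list alone (median -0.17, camera adjusted p = 0.0183, adjusted p = 0.50 with an estimated correlation). That gene was Ms4a3, which encodes a membrane protein and not a granule protein, at 1.27-fold. The megakaryocyte list had a median of -0.43 (camera adjusted p = 0.0245; adjusted p = 0.53 with an estimated correlation), with 0 of 8 genes past the threshold and 1 down adjusted over the list alone. In the type I interferon response 3 of 20 genes fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone (median -0.16, camera adjusted p = 1.35e-03; adjusted p = 0.17 with an estimated correlation). Ddx58, a sensor of viral RNA, was 1.93-fold lower. With the block 18 neutrophil maturation, 2 primary granule, 1 megakaryocyte and 8 interferon genes fell, and 1 interferon gene rose.

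The remaining lists in wt had at most a few single genes past the threshold. Cholesterol synthesis (median 0.21, camera adjusted p = 0.0183; adjusted p = 0.58 with an estimated correlation) and lysosome genes (median -0.20, camera adjusted p = 0.0183; adjusted p = 0.53 with an estimated correlation) were past the threshold as sets with 0 of 18 members each, and 0 adjusted over the list alone. With the block, 5 cholesterol genes rose and 8 lysosome genes fell. The unfolded protein response had 1 of 14 genes down, Edem1, also 1 adjusted over the list alone (median -0.07, camera adjusted p = 0.0351; adjusted p = 0.53 with an estimated correlation). Monocyte and macrophage genes (median -0.31, 1 of 21 down, Fcgr4 at 2.28-fold, 1 adjusted over the list alone) missed the threshold as a set (camera adjusted p = 0.148; 0.0297 with the block; adjusted p = 0.42 with an estimated correlation). So did immediate early genes (median -0.19, 1 of 22 down, Btg2, 1 adjusted over the list alone; 0.0889; 0.00328 with the block; adjusted p = 0.24 with an estimated correlation). Dendritic cell and MHC class II genes had 0 of 12 past the threshold (median -0.15, 0.119; 0.0275 with the block; adjusted p = 0.39 with an estimated correlation) and 0 adjusted over the list alone. Mitosis (2 of 28 down, Nusap1 and Mki67), p53 targets (1 up, Aen, and 1 down, Apaf1, of 19), the erythroid list (1 of 10 up, Klf1 at 1.82-fold) and the Myc and Max network were not past the threshold as sets (camera adjusted p = 0.148, 0.267, 0.149 and 0.45), with the same member counts adjusted over the list alone for the 3 lists named before the network. In the network Myc, Mga and Max rose and Mxd3 fell, and 3 rose and 2 fell adjusted over the list alone; its median was 0.07 and its mean -0.02. The eosinophil list had a median of -0.46 with 0 of 7 genes past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0535). With only genes above the median intensity of all probe sets, it passed (0.0476), while DNA replication (0.138), cholesterol synthesis (0.107), megakaryocyte (0.0548) and unfolded protein response (0.0548) did not. Stem and progenitor (21 genes), B lymphoid (10) and T lymphoid (9) lists had 0 members past the threshold, 0 adjusted over the list alone and camera adjusted p between 0.135 and 0.569. With the block 2 unfolded protein response, 5 immediate early, 1 dendritic cell and MHC class II, 2 stem and progenitor and 1 T lymphoid genes fell, and 2 erythroid genes rose. Also with the block, monocyte and macrophage genes had 2 up and 4 down, mitosis 2 up and 3 down, p53 targets 6 up and 2 down, and the Myc and Max network 3 up and 2 down.

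In wt, limma called 1851 of 19938 genes past adjusted p 0.05, 1231 higher and 620 lower with Myc. Of these 120 changed at least 2-fold, 42 higher and 78 lower. With the replicate number as a block the count was 4082 (2438 higher, 1644 lower). It was 1172 without Myc wt 1, 1209 without GFP wt 1, 859 without Myc wt 3 and 838 without GFP wt 3. Of the 79 genes past the threshold that the naming rule picks, 38 kept their call without each array in turn; those that did not include Slc6a15, Reep6, Gzmb, Serpinb10, AA467197, Inhba and Plbd1, and the highest adjusted p over the 79 was 0.185.

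Adding Myc to cells labelled Zfx ko raised genes for making ribosomes, nucleotides, tRNA synthetases and mitochondrial ribosomes, raised DNA replication and erythroid genes, and lowered neutrophil and mast cell genes. This comparison asks which genes Myc changes when Zfx is deleted per the labels. The largest rises were in Bex4 at 4.89-fold (95% interval 1.96 to 12.2, adjusted p = 2.95e-02), Reep6 at 4.76-fold (2.9 to 7.8, adjusted p = 2.07e-03) and Slc4a1, the anion exchanger of red cells, at 4.54-fold (adjusted p = 3.93e-02). Slc6a15, Tet1, Tlcd4, Cenpv, Ank1, Echdc2 and Spats2 rose between 3.07-fold and 3.83-fold. Mcpt2 was 22.8-fold lower (9.99 to 51.9, adjusted p = 1.04e-03), Gzmb 10.4-fold lower (adjusted p = 4.92e-03) and Npy, a neuropeptide gene, 10.3-fold lower (6.55 to 16.2, adjusted p = 4.09e-04). Serpinb10 was 7.7-fold lower and Mmp9, a gelatinase of neutrophils, 7.56-fold lower (adjusted p = 1.43e-02). Tph1, which starts serotonin synthesis, Mmrn1, AA467197, Fcer1a and Cd96 fell between 3.74-fold and 5.69-fold.

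Ribosome biogenesis rose in 41 of 44 genes in ko and in 44 adjusted over the list alone, with 0 down (median 0.58, camera adjusted p = 4.76e-30; adjusted p = 0.12 with an estimated correlation). Rrp9 rose 1.89-fold, Wdr74 1.84-fold and Gnl3 1.72-fold. Nucleotide synthesis had 16 of 26 up, 19 adjusted over the list alone, and 0 down (median 0.48, camera adjusted p = 3.27e-13; adjusted p = 0.12 with an estimated correlation). Ctps, which makes CTP, rose 1.9-fold, Adsl and Prps1 1.7-fold and Cad 1.62-fold. The tRNA synthetases had 15 of 18 up, 18 adjusted over the list alone, and 0 down (median 0.45, camera adjusted p = 7.12e-13; adjusted p = 0.12 with an estimated correlation). The mitochondrial ribosome had 42 of 74 up, 57 adjusted over the list alone, and 0 down (median 0.35, camera adjusted p = 1.07e-22; adjusted p = 0.12 with an estimated correlation), with Mrpl9 at 1.76-fold and Mrps5 at 1.67-fold. Oxidative phosphorylation had 15 of 30 up, 20 adjusted over the list alone (median 0.25, camera adjusted p = 3.08e-10; adjusted p = 0.12 with an estimated correlation), and the citrate cycle 7 of 13, 8 adjusted over the list alone (median 0.25, camera adjusted p = 3.48e-06; adjusted p = 0.17 with an estimated correlation); 0 fell in either. DNA replication had 14 of 35 up, 19 adjusted over the list alone, and 0 down (median 0.20, camera adjusted p = 3.36e-09; adjusted p = 0.12 with an estimated correlation). Pola2, a subunit of the polymerase that starts new strands, rose 1.39-fold and Rpa2, which binds DNA strands, 1.36-fold. Proteasome genes rose in 6 of 39 cases, 6 adjusted over the list alone and 18 with the block, where 1 fell (median 0.20, camera adjusted p = 4.72e-06; adjusted p = 0.41 with an estimated correlation). Glycolysis had 2 of 15 up, Slc16a1 and Ldha, and 3 adjusted over the list alone, and was not past the threshold as a set (median 0.09, camera adjusted p = 0.115). Srm again was the 1 polyamine gene up, at 1.4-fold, and 2 rose adjusted over the list alone. With the block 4 glycolysis and 2 polyamine genes rose.

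The erythroid list rose in ko with Myc. Of its 10 measured genes 6 rose, 8 adjusted over the list alone, and 0 fell; its median was 1.12, with 0.44, 1.02 and 1.95 in pairs 1, 2 and 3 (camera adjusted p = 1.87e-05; adjusted p = 0.23 with an estimated correlation). Klf1, the erythroid transcription factor, rose 2.88-fold (2.02 to 4.11, adjusted p = 2.72e-03), Ank1, of the red cell membrane skeleton, 3.13-fold and Ermap 2.39-fold. Neutrophil maturation fell in 12 of 19 genes, 17 adjusted over the list alone, and 0 rose (median -0.93, camera adjusted p = 2.23e-13; adjusted p = 0.12 with an estimated correlation). Chil3, a secreted lectin of myeloid cells, was 2.98-fold lower (adjusted p = 1.04e-03). Mast cell and basophil genes fell in 7 of 15 cases, 9 adjusted over the list alone, and 0 rose (median -0.62, camera adjusted p = 2.82e-07; adjusted p = 0.12 with an estimated correlation). Slc18a2, which loads histamine into granules, was 2.8-fold lower (adjusted p = 1.81e-03). The megakaryocyte list had 1 of 8 down, Clec1b at 2.51-fold, also 1 adjusted over the list alone and 4 with the block (median -0.66, camera adjusted p = 2.61e-03; adjusted p = 0.41 with an estimated correlation). In the primary granule list Ms4a3, at 1.33-fold, was the 1 of 6 genes down, with 3 adjusted over the list alone (median -0.26, camera adjusted p = 2.89e-03, adjusted p = 0.39 with an estimated correlation). The interferon list had 5 of 20 down, 6 adjusted over the list alone, and 0 up (median -0.22, camera adjusted p = 1.76e-04; adjusted p = 0.12 with an estimated correlation), with Ddx58 1.85-fold and Usp18 1.47-fold lower. In the stem and progenitor list Cd34 was 2.02-fold and Erg 1.62-fold lower, 2 of 21 genes and 2 adjusted over the list alone, without a shift of the set (camera adjusted p = 0.334). The amino acid and integrated stress response list had 5 of 19 up, among them Stc2 at 1.92-fold and the asparagine synthetase gene Asns at 1.52-fold, and 1 down, Vldlr, with 8 up and 1 down adjusted over the list alone (median 0.13, camera adjusted p = 1.06e-02; adjusted p = 0.41 with an estimated correlation). The unfolded protein response had 3 of 14 down, Edem1, Dnajc3 and Calr, also 3 adjusted over the list alone (median -0.14, camera adjusted p = 1.76e-03; adjusted p = 0.41 with an estimated correlation). Lysosome genes had 1 of 18 down, Man2b1, 0 adjusted over the list alone and 7 with the block (median -0.18, camera adjusted p = 9.58e-03; adjusted p = 0.55 with an estimated correlation). Immediate early genes passed as a set with the block (camera adjusted p = 0.0122; adjusted p = 0.28 with an estimated correlation) and without it did not (0.14). With the block 19 neutrophil maturation, 4 primary granule, 8 interferon and 6 unfolded protein response genes fell, and the stem and progenitor list had 2 up and 5 down.

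In ko, limma called 2626 genes, 1711 higher and 915 lower with Myc, 190 of them at least 2-fold (77 higher, 113 lower). With the block the count was 4959 (2895 higher, 2064 lower). It was 1665 without GFP ko 1, 1395 without Myc ko 3 and 1418 in a fit of the ko arrays alone. Of the 92 genes past the threshold that the rule picks, 51 kept their call without each array; Bex4, Slc4a1, Mmp9, Fcer1a, Tph1, Spats2, Edem1, Dnajc3, Calr and Man2b1 are among those that did not, and the highest adjusted p over the 92 was 0.168.

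Averaged over both genotypes, 6 arrays against 6, ribosome biogenesis, tRNA synthetase, mitochondrial ribosome and neutrophil maturation lists had more genes past the threshold than in either genotype. Ribosome biogenesis had 43 of 44 genes up (44 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), the tRNA synthetases 18 of 18 (18 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation) and the mitochondrial ribosome 58 of 74 (65 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Neutrophil maturation had 17 of 19 genes down and 19 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Camera gave these 4 lists adjusted p = 9.29e-31, 5.42e-13, 5.55e-23 and 2.88e-14. Odc1, the first enzyme of polyamine synthesis, rose 1.59-fold (adjusted p = 7.40e-03, 3 of 3 replicate numbers) and Ppbp, a platelet chemokine, was 7.14-fold lower (adjusted p = 8.08e-03). The averaged effect covered 4236 genes, 2628 higher and 1608 lower, and 6380 with the block. Of the 166 genes that changed at least 2-fold more fell, with 46 higher and 120 lower. Immediate early genes (camera adjusted p = 3.52e-03 with the block, against 0.0797; adjusted p = 0.22 with an estimated correlation) and cholesterol synthesis (3.93e-03, against 0.0792; adjusted p = 0.47 with an estimated correlation) passed as sets with the block. Between wt and ko the Myc effects correlated across genes at Pearson r = 0.87 and Spearman rho = 0.74, where genes are not independent replicates. Of the genes called in each genotype 1055 were higher in both, where independence gives 105.6, 507 were lower in both, where it gives 28.5, and 0 went opposite ways. With the block these counts were 2030 and 1345, where independence gives 354 and 170.2, and 2 genes rose with Myc in wt and fell with it in ko. Independence is too low a level here, since both calls use the same estimate of each gene's spread.

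**Figure D2:**
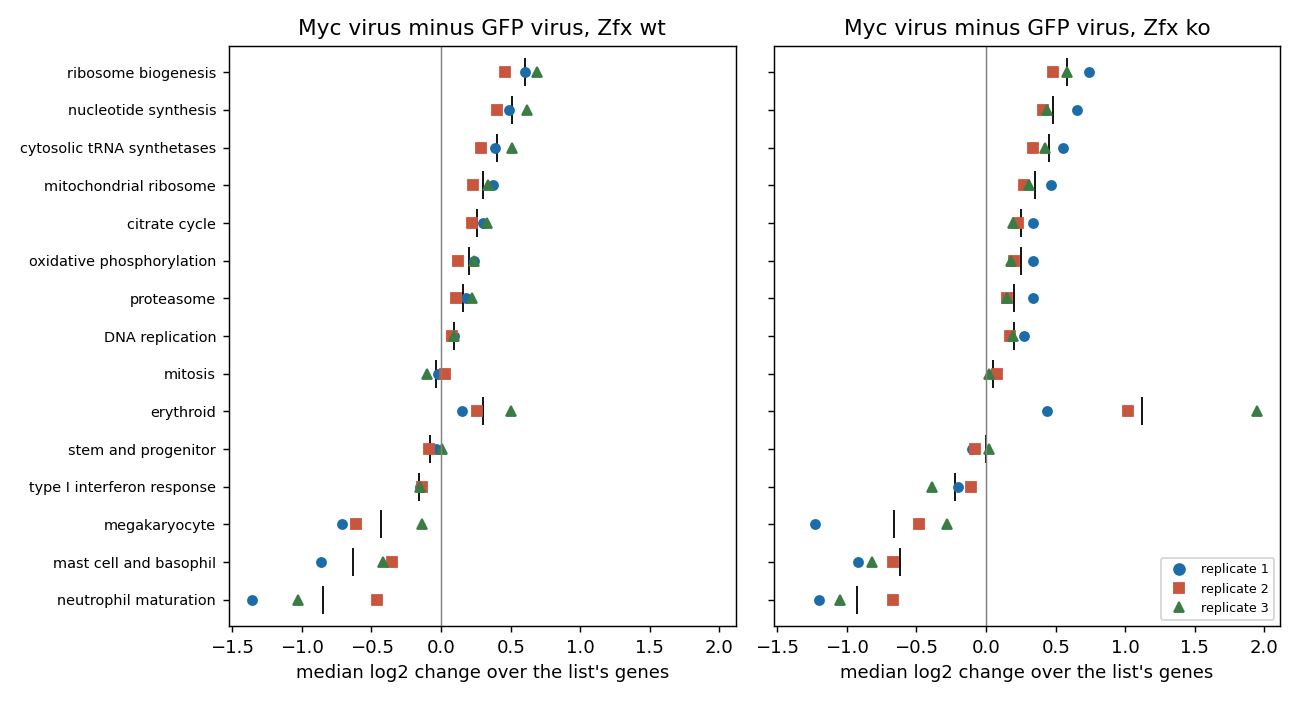
Median log2 change over the genes of 15 lists, Myc virus minus GFP virus, in Zfx wt (left) and Zfx ko (right), with 1 symbol per same-numbered pair of arrays and a black bar for the median of the effects fitted to 3 arrays per group. Ribosome biogenesis lies between 0.46 and 0.69 in the 3 wt pairs and neutrophil maturation between -1.36 and -0.46.

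In cells labelled Zfx ko and grown with the GFP virus, 586 genes were lower and 233 higher than in wt cells. The megakaryocyte list was higher as a set at the preset correlation and did not pass with an estimated one. Most of its genes were past the threshold with the replicate number as a block, and most were not without it. This comparison shows the genotype difference without added Myc. Prss34, a protease of basophils and mast cells, was 8.98-fold lower (95% interval 5.38 to 15, adjusted p = 5.25e-04). Terc, the RNA template of telomerase, was 7.05-fold lower (4.82 to 10.3, adjusted p = 2.10e-04), Cibar1 6.39-fold lower and Phf2, a histone demethylase gene, 6.13-fold lower (5.21 to 7.22, adjusted p = 2.79e-06). Msantd3, Cenpv, Zmynd11, Ptpn9, Lrrc41 and Dis3l were between 4.64-fold and 5.6-fold lower, with adjusted p of 6.35e-04 or less. Npy was 4.63-fold higher (2.94 to 7.29, adjusted p = 2.29e-03) and the transcriptional cofactor Eya1 2.83-fold higher (2.07 to 3.88, adjusted p = 2.61e-03). Lipo3, Casp12, Grb10, Slc6a15, F11r, Mfsd2b, Fnbp1l and Tmem243 were between 2.68-fold and 3.23-fold higher. The mitochondrial enzyme genes fixed in advance were lower: Idh2 (10564857, chromosome 7) by 1.62-fold (1.43 to 1.82, adjusted p = 7.75e-04), from 3250 ± 59.5 to 2010 ± 176, and Ptpmt1 (10484920, chromosome 2) by 2.86-fold (2.28 to 3.58, adjusted p = 3.71e-04), from 995 ± 139 to 351 ± 70.7, each in 3 of 3 pairs.

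Of 8 measured megakaryocyte genes 2 rose in ko with GFP, 7 adjusted over the list alone and 7 with the block, and 0 fell. Clec1b was 2.46-fold and Treml1 2.15-fold higher, both receptors of platelets. The list's median was 1.35, with 1.34, 1.18 and 1.60 in pairs 1, 2 and 3 (camera adjusted p = 1.93e-06; adjusted p = 0.54 with an estimated correlation). Erythroid genes had a median of 0.42 with 0 of 10 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0287; adjusted p = 0.92 with an estimated correlation). Mast cell and basophil genes had 3 of 15 down, Prss34, Mcpt8 at 2.92-fold and Mcpt4 at 1.7-fold, 6 adjusted over the list alone, and 0 up (median -0.49, camera adjusted p = 1.43e-03; adjusted p = 0.86 with an estimated correlation). Primary granule proteins had 0 of 6 past the threshold and 1 down adjusted over the list alone (median -0.18, camera adjusted p = 0.0201; adjusted p = 0.86 with an estimated correlation). The stem and progenitor list did not shift (camera adjusted p = 0.921), but Hoxa9, a homeobox regulator of progenitors, was 2.68-fold lower (2.09 to 3.44, adjusted p = 8.40e-04) and Hoxa5 1.23-fold lower (adjusted p = 5.70e-03), 2 of 21 genes; adjusted over the list alone 3 fell and 2 rose. Mmp8, the neutrophil collagenase, was 2.64-fold higher (adjusted p = 3.14e-03), the 1 of 19 neutrophil genes past the threshold, also 1 adjusted over the list alone (camera adjusted p = 0.357). Monocyte and macrophage genes had 0 of 21 past the threshold and 0 adjusted over the list alone (median 0.28, camera adjusted p = 0.0596; 0.00582 with the block, where 7 rose and 1 fell; adjusted p = 0.72 with an estimated correlation there). With the block mast cell and basophil genes had 6 down and 1 up, primary granule proteins 2 down, and stem and progenitor genes 4 up and 3 down, and 1 erythroid and 2 neutrophil genes rose.

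Few cell division genes differed in ko with GFP. Mitosis had 2 of 28 genes down, Cdk1 at 1.23-fold and Mad2l1 at 1.18-fold, 3 adjusted over the list alone, and 0 up (median -0.12, camera adjusted p = 2.14e-06; adjusted p = 0.54 with an estimated correlation). DNA replication had 3 of 35 down, Pola2, Gins2 at 1.26-fold and Mcm3, also 3 adjusted over the list alone, and 0 up (median -0.09, camera adjusted p = 1.68e-03; adjusted p = 0.86 with an estimated correlation). Interferon genes had 3 of 20 up, Oasl2 at 1.54-fold (adjusted p = 8.17e-04), Usp18 and Rsad2, 4 adjusted over the list alone, and 0 down (median 0.29, camera adjusted p = 3.69e-04; adjusted p = 0.50 with an estimated correlation). The amino acid and integrated stress response list had 1 of 19 up, Vldlr, and 2 adjusted over the list alone (median 0.15, camera adjusted p = 0.0142; adjusted p = 0.86 with an estimated correlation). Cholesterol synthesis had 0 of 18 past the threshold and 0 adjusted over the list alone (median -0.20, camera adjusted p = 0.036; adjusted p = 0.97 with an estimated correlation). Ei24, a p53 target, was 1.85-fold lower (adjusted p = 4.30e-03), the 1 of 19 in its list, and Acp5, a lysosomal acid phosphatase, was 1.94-fold higher (adjusted p = 6.35e-04), the 1 of 18 in its list; each list also had 1 adjusted over the list alone. With the block the lysosome list (camera adjusted p = 0.0294, against 0.0838; adjusted p = 0.88 with an estimated correlation) and the immediate early list (0.00322, against 0.161; adjusted p = 0.42 with an estimated correlation) passed as sets. With only genes above the median intensity of all probe sets, mitosis and megakaryocyte passed as sets, while DNA replication (camera adjusted p = 0.0635), interferon (0.246), mast cell and basophil (0.07), erythroid (0.0583), primary granule (0.0969), amino acid and integrated stress response (0.075) and cholesterol synthesis (0.133) did not. Ribosome biogenesis had 0 of 44 genes past the threshold and 0 adjusted over the list alone (median -0.02, camera adjusted p = 0.805). With the block 4 of the amino acid and integrated stress response list rose, and 3 cholesterol synthesis and 3 ribosome biogenesis genes fell. Interferon genes then had 6 up and 1 down, lysosome genes 3 up and 1 down, and p53 targets 1 up and 1 down.

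With GFP, limma called 819 genes, 233 higher and 586 lower in ko, 131 of them at least 2-fold (46 higher, 85 lower). With the block the count was 2440 (1020 higher, 1420 lower). It was 491 without GFP wt 1, 533 without GFP ko 2, 410 without GFP wt 3 and 524 without GFP ko 3. Of the 43 genes past the threshold that the rule picks, 25 kept their call without each array; Slc6a15, Mfsd2b, Lipo3, Grb10, Casp12, Mcpt8, Mcpt4, Clec1b, Treml1, Cdk1, Mad2l1, Pola2, Mcm3, Usp18, Rsad2 and Vldlr are among those that did not, and the highest adjusted p over the 43 was 0.181.

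With the Myc virus Cibar1, Phf2, Ptpn9, Prss34, Dis3l and Lrrc41 were again among the genes lowered most in ko, with 4 of 15 mast cell genes lower and 4 of 10 erythroid genes higher. This comparison shows the genotype difference under added Myc. Cibar1 was 8.88-fold lower (6.89 to 11.4, adjusted p = 5.52e-06), Smo, which transduces Hedgehog signals, 7.05-fold lower (5.29 to 9.38, adjusted p = 2.01e-05), Zc3h7b 6.95-fold lower, Phf2 6.83-fold lower (adjusted p = 1.54e-06) and the tyrosine phosphatase Ptpn9 6.31-fold lower. Prss34, Mcpt8, Ms4a2, Dis3l and Lrrc41 were between 4.66-fold and 5.44-fold lower. Slc44a1, a choline transporter, was 4.68-fold higher (2.16 to 10.2, adjusted p = 3.00e-02), Cda, cytidine deaminase, 4.58-fold higher (adjusted p = 7.18e-03) and Slc35f2 4.23-fold higher (adjusted p = 2.12e-03). P3h2, Lgmn, Pla2g7, Mfsd2b, Pde5a, Tspan6 and Clec4a3 were between 3.64-fold and 4.24-fold higher. Idh2 was 1.79-fold lower (1.59 to 2.02, adjusted p = 2.46e-04), from 3730 ± 241 to 2080 ± 150, and Ptpmt1 2.09-fold lower (1.67 to 2.62, adjusted p = 2.48e-03), from 1350 ± 61.4 to 648 ± 72.8, each in 3 of 3 pairs.

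Of 10 erythroid genes 4 rose in ko with Myc, 9 adjusted over the list alone, and 0 fell. Ank1 was 3.32-fold, the erythropoietin receptor gene Epor 2.9-fold, Ermap 2.72-fold and Klf1 2.05-fold higher. The list's median was 1.28, with 1.06, 0.95 and 2.05 in pairs 1, 2 and 3 (camera adjusted p = 3.58e-08; adjusted p = 0.53 with an estimated correlation). Megakaryocyte genes had a median of 1.31, with 0 of 8 past the threshold and 6 up adjusted over the list alone (camera adjusted p = 1.27e-04; adjusted p = 0.65 with an estimated correlation). Mast cell and basophil genes had 4 of 15 down, Prss34, Mcpt8, Ms4a2 and the IgE receptor chain Fcer1a, 6 adjusted over the list alone, and 0 up (median -0.50, camera adjusted p = 1.80e-05; adjusted p = 0.53 with an estimated correlation). In the primary granule list Ms4a3 was the 1 of 6 genes down, with 2 adjusted over the list alone (median -0.28, camera adjusted p = 1.51e-03, adjusted p = 0.65 with an estimated correlation). Monocyte and macrophage genes had 1 of 21 up, Lgmn, a lysosomal protease, and 2 adjusted over the list alone (median 0.39, camera adjusted p = 0.013; adjusted p = 0.81 with an estimated correlation). In the stem and progenitor list Meis1 was 3.31-fold higher (adjusted p = 6.59e-03), while Hoxa9 was 2.58-fold lower (adjusted p = 9.71e-04), Gata2 2.63-fold lower and Hoxa5 1.14-fold lower; 3 rose and 4 fell adjusted over the list alone, without a shift of the set (camera adjusted p = 0.851). Among neutrophil genes Mmp8 was 2.13-fold higher and Chil3 2.86-fold lower (adjusted p = 1.26e-03), with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.34). With the block 8 erythroid, 6 megakaryocyte and 6 monocyte and macrophage genes rose and 4 primary granule genes fell. Mast cell and basophil genes then had 6 down and 1 up, stem and progenitor genes 5 up and 5 down, and neutrophil genes 3 up and 1 down.

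Cholesterol synthesis was lower as a set in ko with Myc (median -0.32, camera adjusted p = 1.27e-04; adjusted p = 0.88 with an estimated correlation). Sc5d was the 1 of 18 genes down, 3 adjusted over the list alone and 11 with the block. Interferon genes had 1 up, Oasl2 at 1.42-fold, and 1 down, Bst2 at 1.38-fold, of 20, also 1 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 2.63e-03; adjusted p = 0.53 with an estimated correlation). With only genes above the median intensity of all probe sets, this call was lost (0.339). Ei24 was 1.81-fold and Perp 2.82-fold lower, the 2 of 19 p53 targets past the threshold, also 2 adjusted over the list alone (camera adjusted p = 0.457). With the block the immediate early list (camera adjusted p = 0.00244, against 0.237; adjusted p = 0.43 with an estimated correlation) and the dendritic cell and MHC class II list (0.0323, against 0.295; adjusted p = 0.66 with an estimated correlation) passed as sets. Cholesterol synthesis aside, the growth lists that rose with Myc were not past the threshold as sets in this comparison. DNA replication was lower as a set with GFP at the preset correlation. Ribosome biogenesis had 0 of 44 genes past the threshold with Myc and 0 adjusted over the list alone (median -0.01, which is 0.01 after a further quantile normalization, camera adjusted p = 0.975). With the block interferon genes had 2 up and 1 down, and p53 targets 1 up and 3 down.

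With Myc, limma called 1089 genes, 347 higher and 742 lower in ko, 192 of them at least 2-fold (82 higher, 110 lower). With the block the count was 2808 (1207 higher, 1601 lower). It was 721 without Myc wt 1, 691 without Myc wt 2, 578 without Myc wt 3, 639 without Myc ko 3 and 562 in a fit of the Myc arrays alone. Of the 46 genes past the threshold that the rule picks, 30 kept their call without each array; P3h2, Pde5a, Lgmn, Slc44a1, Klf1, Fcer1a, Gata2, Hoxa5, Ms4a3, Sc5d and Perp are among those that did not, and the highest adjusted p over the 46 was 0.171.

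**Figure D3:**
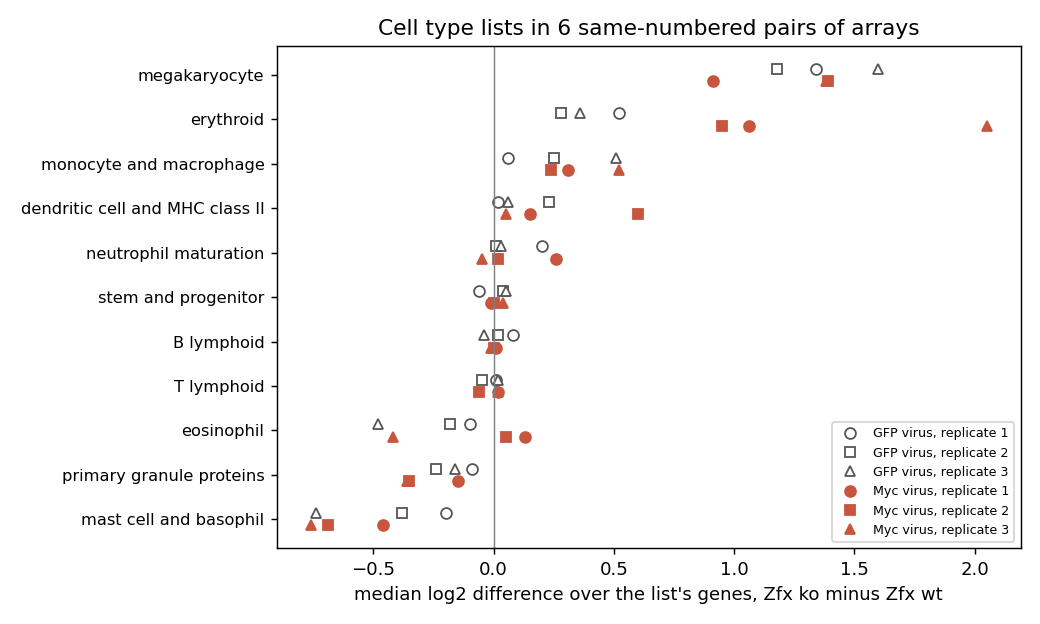
Median log2 difference over the genes of 11 cell type lists, Zfx ko minus Zfx wt, in 6 same-numbered pairs of arrays (open symbols GFP virus, filled symbols Myc virus, shape gives the replicate number). The megakaryocyte list lies between 0.91 and 1.60 and the erythroid list between 0.28 and 2.05, while the mast cell and basophil list lies between -0.76 and -0.20.

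Averaged over both viruses, 6 arrays against 6, the platelet lineage stood out among genes higher in ko. Of 8 megakaryocyte genes 7 rose, also 7 adjusted over the list alone (median 1.27, camera adjusted p = 7.73e-06; adjusted p = 0.48 with an estimated correlation). They include Pf4, platelet factor, at 3.11-fold (adjusted p = 1.48e-02), Vwf, von Willebrand factor, at 2.7-fold (adjusted p = 1.83e-02) and the integrin gene Itga2b at 2.42-fold (adjusted p = 1.46e-02). Erythroid genes had 5 of 10 up, 7 adjusted over the list alone (median 0.92, camera adjusted p = 1.24e-05; adjusted p = 0.48 with an estimated correlation), and mast cell and basophil genes 5 of 15 down, 8 adjusted over the list alone (median -0.47, camera adjusted p = 1.94e-05; adjusted p = 0.48 with an estimated correlation). Penk, the enkephalin precursor gene, had the largest rise, at 5.62-fold (2.33 to 13.5, adjusted p = 1.70e-02), and Peg10 was 3.7-fold higher (adjusted p = 9.74e-03). Cibar1 was 7.53-fold lower (6.3 to 9.01, adjusted p = 3.12e-07), Phf2 6.47-fold (adjusted p = 5.81e-08) and Terc 5.23-fold (adjusted p = 1.82e-05), and Idh2 was 1.7-fold (adjusted p = 1.59e-05) and Ptpmt1 2.45-fold lower (adjusted p = 3.11e-05). Of these Pf4, Vwf, Itga2b, Idh2 and Ptpmt1, which were not chosen for arrays that do not overlap, moved the same way in 3 of 3 replicate numbers. The Myc probe set differed by -0.10 ± 0.05 (log2, SE; adjusted p = 0.282, 0.0316 with the block, 3 of 3). The averaged effect covered 2406 genes, 943 higher and 1463 lower, and 4583 with the block (2093 higher, 2490 lower). Of the 197 genes that changed at least 2-fold, 100 were higher and 97 lower. With the block mast cell and basophil genes had 9 down and 1 up.

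The genotype effects under the 2 viruses were alike gene by gene. They correlated across genes at Pearson r = 0.84 and Spearman rho = 0.67, with r = 0.75, 0.80 and 0.67 for replicate numbers 1, 2 and 3. The comparisons share no arrays, but genes are not independent replicates. Same-numbered arrays of 1 genotype also varied together across the viruses (correlations of 0.44 to 0.79). The 2 comparisons are therefore not shown to be independent of each other. Of 32 swaps of genotype labels within same-numbered pairs 1, the real one, gave as high an r, and the highest other gave 0.66. Of the genes called under each virus 464 were lower in both, where independence gives 21.8, among them Cibar1, Phf2, Ptpn9, Terc, Idh2 and Ptpmt1. In the same way 141 were higher in both, where independence gives 4.1, and 0 went opposite ways. With the block 1041 were lower in both and 670 higher in both, where independence gives 114 and 61.7, and 0 went opposite ways. The averaged Myc and Zfx effects had r = -0.06 and rho = -0.03 across genes, with r = -0.21, -0.04 and 0.02 and rho = -0.23, 0.01 and 0.06 for replicate numbers 1, 2 and 3. Among genes called for both averaged effects, 412 were higher with Myc and lower in ko, 208 higher in both, 183 lower with Myc and higher in ko, and 232 lower in both, where independence gives 192.8, 124.3, 76.1 and 118. With the block these counts were 840, 529, 601 and 579, where it gives 458.3, 385.3, 284.5 and 338.4. Each of these counts exceeds independence although the averaged effects hardly correlated. Both calls use the same estimate of each gene's spread, so a count above independence does not by itself show alike effects. The genotype effects under the 2 viruses differ from this in that 0 called genes went opposite ways.

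**Figure D4:**
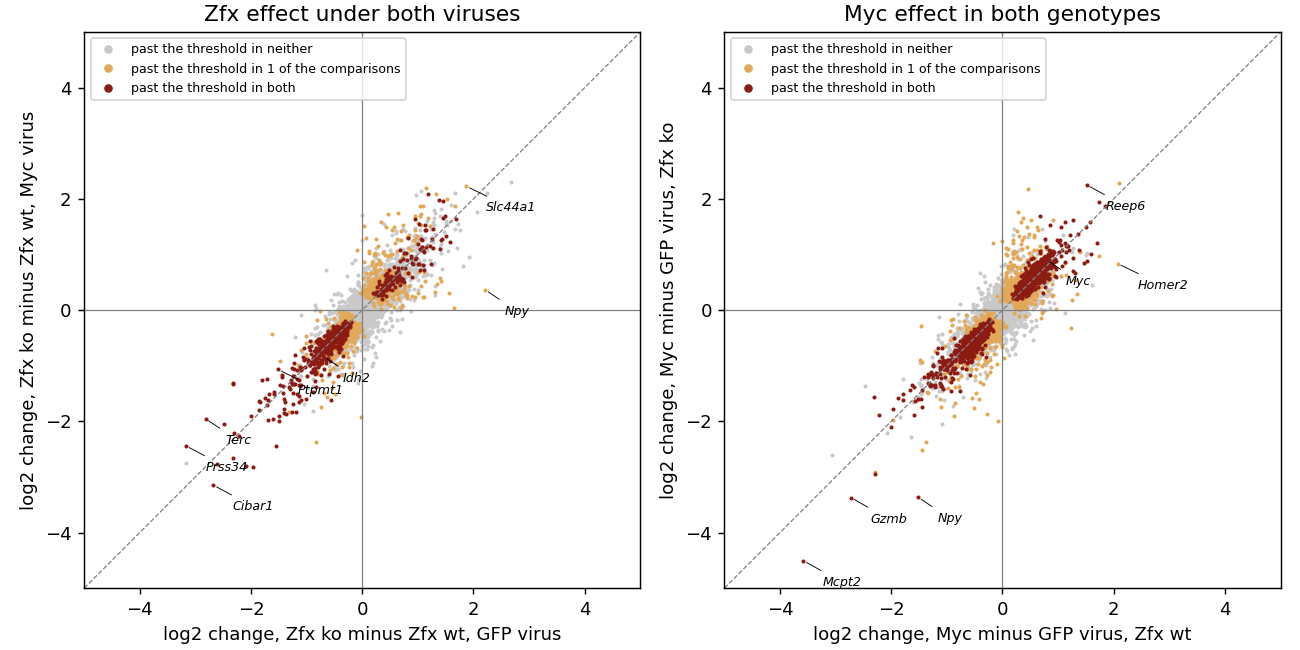
Log2 changes of all 19938 genes, for the Zfx effect with the GFP virus against that with the Myc virus (left) and for the Myc effect in Zfx wt against that in Zfx ko (right), coloured by whether a gene passed adjusted p 0.05 in neither, 1 or both of the comparisons (n = 3 arrays per group; dashed line, equal change). Pearson r across genes is 0.84 on the left and 0.87 on the right.

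Whether the Myc response depends on Zfx was tested gene by gene as the difference between the Myc effects in ko and wt. Limma called 0 genes; 343 had an unadjusted p under 0.05, where about 997 would by chance. The lowest p belonged to the receptor gene Lgr4 (log2 difference -1.06 ± 0.14 SE, adjusted p = 0.312), Pkhd1l1 (0.81, adjusted p = 0.632), Cenpv (1.02, adjusted p = 0.639), Ncs1 (-0.76, adjusted p = 1) and Cysltr2 (-0.52, adjusted p = 1), none of them past the threshold. Idh2 (-0.15) and Ptpmt1 (0.45 ± 0.21) also had adjusted p = 1. With the block 1 gene passed, Nck2 (log2 difference -0.80, adjusted p = 0.0198 with the block), named after its values were seen, and 939 had an unadjusted p under 0.05. That is near the 997 by chance, so the limma p-values without the block were too large for this contrast. The other contrasts use the same estimate of the spread, so the same may hold for them. Their counts without the block may therefore be too low, as with 819 against 2440 genes for Zfx with GFP. Without Myc wt 1 the count was 1 (Lgr4), and without Myc ko 1 it was 4 (Arpin, Epb42, Lin28b and Pkhd1l1, of which Arpin, Epb42 and Lin28b were named after their values were seen).

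Some lists shifted between the Myc responses as sets, with 0 members past the threshold and 0 adjusted over the list alone. The erythroid list had a larger Myc effect in ko, with a median difference of 0.85 and 0.46, 0.78 and 1.47 in replicate numbers 1, 2 and 3 (camera adjusted p = 3.86e-08; adjusted p = 0.48 with an estimated correlation). DNA replication differed by 0.15, with 0.19, 0.10 and 0.11 (camera adjusted p = 1.52e-10; adjusted p = 0.48 with an estimated correlation). Glycolysis differed by -0.16, with 0.02, -0.06 and -0.36 (camera adjusted p = 4.15e-04; adjusted p = 0.82 with an estimated correlation). Mitosis (0.06, camera adjusted p = 7.18e-04; adjusted p = 0.82 with an estimated correlation), the mitochondrial ribosome (0.06, camera adjusted p = 5.04e-03; adjusted p = 0.87 with an estimated correlation) and cholesterol synthesis (-0.14, camera adjusted p = 0.0281; adjusted p = 0.87 with an estimated correlation) also passed. With the block p53 targets (camera adjusted p = 0.0328, against 0.106; adjusted p = 0.79 with an estimated correlation) and the dendritic cell and MHC class II list (0.022, against 0.164; adjusted p = 0.79 with an estimated correlation) passed as well. Mast cell and basophil genes had a median difference of -0.27, with 0.03, -0.32 and -0.58, 0 of 15 genes past the threshold and 2 lower adjusted over the list alone. They did not pass as a set (camera adjusted p = 0.106), but did with only genes above the median intensity of all probe sets (8.24e-05). With an estimated correlation over all genes they did not pass.

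The size of the Myc response was compared over the 4236 genes called for the averaged Myc effect, a choice that does not bias the difference between genotypes. Of these genes 65.1% had the larger Myc effect in ko, with 70.0%, 63.7% and 49.2% in replicate numbers 1, 2 and 3. Simulated data without a genotype difference gave 48.1% to 51.8%. The simulation drew each gene independently and left out variation that genes share. Its range is therefore too narrow to judge the real share by. The ratio of the ko to the wt effect was 1.11 over genes that rose, with 1.25, 1.24 and 0.923 by replicate number, and 1.13 over genes that fell, with 1.15, 1.04 and 1.18. The share was 53.3% without GFP ko 1, 53.4% without Myc wt 2 and 54.2% without GFP wt 2, and 7 of the 32 swaps of genotype labels within same-numbered pairs lay as far from 50%.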

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

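The camera tests were set before the results were seen, and the count of probe sets without a single gene symbol was chosen after. Camera with a preset correlation found 6 lists whose Myc effect differed between the genotypes, each a test of the difference itself, and none of them passed with an estimated correlation. The erythroid list had a median difference of 0.85 (log2, ko minus wt) and DNA replication one of 0.15. Mitosis and the mitochondrial ribosome each had a median difference of 0.06. For glycolysis the median difference was -0.16 and for cholesterol synthesis -0.14.

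Probe sets without a single gene symbol were outside the gene comparisons. Of 13767 such probe sets limma called 298 for the averaged Zfx effect, 140 higher and 158 lower in ko. That is 2.16% of them, against 9.16% of probe sets with 1 symbol. With the replicate number as a block it called 917, 459 higher and 458 lower, which is 6.66% against 18.58%.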

How the results depend on the processing

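The alternatives were chosen before the data were examined, and except where a reason is given the cause was not tested. With the replicate number as a block the count of genes past the threshold was 4082 for Myc in wt, 4959 for Myc in ko, 2440 for Zfx with GFP, 2808 for Zfx with Myc, 1 for the interaction, 6380 for the averaged Myc effect and 4583 for the averaged Zfx effect, and the genes called without the block were all called with it. The block also moved the Myc probe set past the threshold between genotypes with GFP and on average, Nck2 for the interaction, and the list calls given with their blocked values elsewhere in the text. Beyond these it changed the call of no gene that the naming rule picks. Array weights gave 3209 genes for Myc in wt and 1610 for Zfx with GFP. Fits of only the groups compared gave 1418 for Myc in ko and 562 for Zfx with Myc, with fewer arrays to estimate the spread. All probe sets gave a correlation of the Zfx effects of 0.766. By construction a 2-fold minimum lowers counts, to 120 for Myc in wt (42 higher, 78 lower), 190 for Myc in ko (77 and 113), 131 for Zfx with GFP (46 and 85), 192 for Zfx with Myc (82 and 110), 166 for the averaged Myc (46 and 120) and 197 for the averaged Zfx effect (100 and 97). With an estimated correlation camera passed 0 lists in each of the 7 contrasts, where the preset one passed 18 for Myc in wt, 17 for Myc in ko, 9 for Zfx with GFP, 7 for Zfx with Myc, 6 for the interaction, 18 for the averaged Myc and 8 for the averaged Zfx effect. With only genes above the median intensity of all probe sets, 2 lists passed for Zfx with GFP, mitosis and megakaryocyte, and 15 for Myc in wt, 17 for Myc in ko, 6 for Zfx with Myc, 7 for the interaction, 18 for the averaged Myc and 7 for the averaged Zfx effect. The interferon list lost its call in each of the 3 Zfx comparisons, and mast cell and basophil gained one for the interaction. Leaving out each array in turn gave 838 to 2044 genes for Myc in wt, 1395 to 2555 for Myc in ko, 410 to 802 for Zfx with GFP, 578 to 1098 for Zfx with Myc and 0 to 4 for the interaction, where the 4 came without Myc ko 1 and 1 came without Myc wt 1. The share of genes with the larger Myc effect in ko was 53.3% to 74% and the correlation of the Zfx effects 0.75 to 0.836. The counts for the averaged effects stayed within 1.5 times, at 3538 to 4154 for Myc and 1792 to 2272 for Zfx. Among 448 calls of named genes, 0 changed direction under the alternatives counted here gene by gene, which leave out all probe sets and the 2-fold minimum; 52 were lost with centring, 2 with only genes above the median intensity of all probe sets (417 kept), 88 with only the groups compared (172 kept), 25 with a second quantile normalization, 24 with the trended prior, 4 with array weights and 0 with the block. Over the 12 fits without 1 array, 793 combinations of call and array lost the call and 4583 kept it. Small differences of Zfx, Zfy1 and Zfy2, none past the threshold, changed sign. For the averaged Zfx effect these were Zfy2 at 0.004 with a second quantile normalization and 0.03 with array weights, and Zfy1 at -0.006 with centring and -0.031 with array weights. For Myc in ko they were Zfy1 at 0.007 with centring and 0.011 with array weights, and Zfx at -0.042 with array weights. For Zfx with GFP it was Zfy1 at -0.023 with array weights. Leaving out arrays, Zfy1 ranged from -0.008 to 0.053 for Myc in wt, -0.01 to 0.058 for Zfx with GFP, -0.015 to 0.016 for the averaged Myc and -0.017 to 0.017 for the averaged Zfx effect. Zfy2 ranged from -0.031 to 0.045 for Myc in wt, -0.191 to 0.02 for Myc in ko, -0.16 to 0.05 for Zfx with Myc, -0.202 to 0.008 for the interaction, -0.09 to 0.015 for the averaged Myc and -0.06 to 0.045 for the averaged Zfx effect. Zfx ranged from -0.008 to 0.09 for Myc in ko and -0.078 to 0.034 for the interaction. Intensities of Zfy1 and Zfy2 lay near the lowest on the arrays, which limits what their differences can show.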

Other observations

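The tests chosen after the results were seen are those on the Zfx probe set, on the megakaryocyte and erythroid lists, on swaps of the virus labels and on the share of genes with the larger Myc effect; the other tests were set beforehand. Averaged over both viruses, cholesterol synthesis genes were lower in ko, with Insig1, which restrains sterol synthesis, 1.46-fold, Sc5d 1.36-fold and Mvk, mevalonate kinase, 1.18-fold lower. They are 3 of 18 genes, 5 adjusted over the list alone and 12 with the block (median -0.26, camera adjusted p = 6.96e-04; adjusted p = 0.93 with an estimated correlation). Interferon genes had 5 of 20 up and 1 down, 8 up and 2 down adjusted over the list alone (median 0.24, camera adjusted p = 3.07e-04; adjusted p = 0.48 with an estimated correlation), with Oasl2 1.48-fold higher (adjusted p = 5.96e-05, 3 of 3 replicate numbers). With only genes above the median intensity of all probe sets the interferon list did not pass (0.301). Monocyte and macrophage genes had 2 of 21 up, Lgmn at 3.39-fold and the lipid receptor Trem2 at 1.89-fold, and 4 adjusted over the list alone (median 0.39, camera adjusted p = 0.0152; adjusted p = 0.75 with an estimated correlation). Mitosis had 5 of 28 genes down and 6 adjusted over the list alone (median -0.08, camera adjusted p = 2.11e-04, adjusted p = 0.54 with an estimated correlation). In the primary granule list Ms4a3 and Elane, neutrophil elastase, were down, 2 of 6 genes and 4 adjusted over the list alone (median -0.23, camera adjusted p = 1.95e-03, adjusted p = 0.61 with an estimated correlation). With the block 8 mitosis and 5 primary granule genes were down, interferon genes had 9 up and 2 down, and monocyte and macrophage genes had 8 up and 1 down.

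Single genes moved in lists that did not shift as a set. In the stem and progenitor list Hoxa9 was 2.63-fold lower (adjusted p = 3.63e-05) and Gata2 1.96-fold lower, while its partner gene Meis1 was 2.62-fold higher (adjusted p = 1.41e-03) and Slamf1, a surface receptor of stem cells, 3.04-fold higher, each in 3 of 3 replicate numbers. That is 4 of 21 genes down and 2 up, 5 and 5 adjusted over the list alone (camera adjusted p = 0.957). In the citrate cycle Idh2, Dld and Dlst were lower, 3 of 13 and 3 adjusted over the list alone (camera adjusted p = 0.328). In the mitochondrial ribosome 6 of 74 genes were lower, among them Mrps26 at 1.41-fold and Mrpl14 at 1.37-fold, and 1 was higher, Mrpl52 at 1.49-fold; adjusted over the list alone 4 were lower and 1 higher (camera adjusted p = 0.958). With the block 9 of these were lower and 6 higher, and the stem and progenitor list had 6 down and 6 up. Immediate early genes (camera adjusted p = 7.61e-04 with the block, against 0.14; adjusted p = 0.41 with an estimated correlation) and the amino acid and integrated stress response (0.0391, against 0.0562; adjusted p = 0.60 with an estimated correlation) passed as sets with the block and not without it. Slamf1, Insig1 and Dld were among the 19 of 82 named genes that lost their call without at least 1 array.

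The Zfx probe set was not lower in arrays labelled Zfx ko. That these arrays do not differ from the wt arrays is argued against by swapping genotype labels within same-numbered pairs: 1 of 32 swaps, the real one, gave 4583 genes with the block, and the highest other gave 1. This shows a difference between the arrays and does not show that it is the deletion of Zfx. Cis effects of strain variants linked to Zfx could account only for genes on chromosome X. Of the called genes 2.74% lie on X, against 3.71% of all genes, which argues against such effects for the called genes as a set. They could still act on a few genes near Zfx, and no test by position was made. A probe set that lies outside the deleted part may keep its signal, and with an averaged difference of 0.09 and no probe positions this cannot be told apart from a gene that was not deleted.

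Megakaryocyte and erythroid lists were higher and the mast cell list was lower in ko (adjusted p = 0.48 with an estimated correlation for each). A lower share of the main cell type would raise all other lists alike. The megakaryocyte median exceeded that of each of 4 other myeloid lists by at least 0.6 (log2) in the 6 same-numbered pairs (spread 0.45). That list was picked for its rise in these same pairs, so its lead is partly given by the choice and is no independent test. The erythroid median exceeded that of the mast cell list by 1.41 on average, where the spread is 0.8, and by at least 0.66 in each pair. It exceeded that of the eosinophil list by 1.04 on average (spread 0.72) and by at least 0.46. The erythroid list was also picked for its rise in these pairs, and the mast cell list for its fall. These gaps are thus partly given by the choice as well. Over the monocyte list the erythroid median led in 5 of 6 pairs (lowest -0.15), by 0.55 on average (spread 0.6). With GFP that lead was 0.11 (spread 0.31) and with Myc 0.99 (spread 0.47). With GFP the erythroid list thus did not move apart from the monocyte list. A lower share of the main type is not excluded by either set of values. More cells of these lineages and more transcript per cell cannot be told apart for the median difference of 1.27, because bulk RNA gives 1 value per gene and array. The genotype itself stays open as an untested explanation, and counts of cells by lineage were not analysed here.

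The genes lower in ko under both viruses might reflect fewer mast cells and basophils. Outside the mast cell list they number 462, with a median averaged Zfx effect of -0.56. If they moved as the mast cell list does, their median Myc effect would be -0.90. It was 0.1 (0.07 to 0.13 over resampled genes), so as a set they did not follow the mast cell list under Myc. The comparison takes the Myc effects as a matter of cell numbers, which was not tested. It therefore does not decide whether fewer mast cells and basophils lowered these genes in ko. The count of 464 was reached in 1 of 32 swaps of genotype labels within same-numbered pairs, the real one, with 0 in the highest other. That is the lowest share 32 swaps can give, which argues against chance without excluding it. Which other property these genes share was not tested.

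Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave the highest count in each comparison, 1 of 10, with 1851 genes for Myc in wt (highest other 1), 2626 for Myc in ko (0), 819 for Zfx with GFP (0) and 1089 for Zfx with Myc (0). Among the 4 splits that part 3 pairs, the highest other was 0 in each; the others part fewer pairs. For the averaged effects the splits argue against chance. The real split alone, 1 of 100, gave 4236 genes for Myc (highest other 1138) and 1 of 100 gave 2406 for Zfx (highest other 932). These splits disregard the replicate numbers. Swapping labels within same-numbered pairs, 1 of 32 swaps, the real one, gave 4236 genes for Myc (highest other 0) and 1 of 32 gave 2406 for Zfx (highest other 1). For the interaction, where limma called 0 genes (343 at an unadjusted p under 0.05), 100 of 100 splits gave as many and the highest other gave 0. No split can give fewer than 0, so these splits say nothing about chance. For the share of genes with the larger Myc effect in ko chance cannot be excluded: 7 of 32 swaps lay as far from 50%, where the real distance was 15.1 points and the highest other 24.6.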
